A study of Mus musculus with 5 samples.

How the data were processed

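The samples were tibialis anterior muscles of C57BL/6J male mice, uninjected or taken 1, 3, 4, 7 or 21 days after intramuscular cardiotoxin, with 4 mice per time point per the labels. Total RNA was isolated with a miRNeasy kit, RNA with an integrity number above 9 was used, and TaqMan assays were run for 40 cycles on a 7900HT instrument, per the labels' protocols. The deposited files held raw Ct values as the authors exported them, with no normalization, in a column for the time point and a column for the baseline. How the Ct threshold was set, how much RNA entered each reaction and which genome build or miRNA release the assays were designed on are not given in the sources used here. Depth has no counterpart in these data, and the number of wells per arm limits the precision.

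Each file listed 222 assays in 888 lines, 4 Ct values per assay and arm. The baseline values were identical in the 5 files and were used once, which left 5328 distinct Ct values in 6 arms. The values were taken as the 4 mice of an arm, which the files do not state. Whether the nth value of each assay came from the same RNA was checked within arms: of 1000 shuffles, 0, 0, 6, 0, 0 and 3 gave as large a leading component of the deviations at baseline and on days 1, 3, 4, 7 and 21. No pair of values in an arm looked like a copy, with median absolute differences between 0.11 and 0.56 cycles. The smallest was that of values 2 and 3 of day 7, where the other pairs of that arm differed by 0.26 to 0.33.

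A miRNA counted as detected in an arm with a Ct under 35 in at least 3 of 4 wells, and was tested only where detected in both arms. Wells at 40, the last cycle, were left out of the fit. For a miRNA detected in 1 arm only, the wells of the other arm were set to Ct 35 where they exceeded it, and the resulting fold is a lower bound. The main values were minus delta Ct against U6, which the files mark as the endogenous control. Because U6 differed between arms, a second scaling was added after seeing the data: each well's median change of 205 miRNAs, those under Ct 35 in every well, from their baseline mean ("relative to the median miRNA").

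All 6 arms entered a single fit per miRNA with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with contrasts of each time point against baseline and of successive time points. P-values were adjusted by Benjamini-Hochberg over the miRNAs tested in a contrast, two-sided, and a miRNA passed at an adjusted p under 0.05. Errors of changes are the fit's standard errors. Of 15 lists written before the data were examined, 13 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, with the correlation estimated from the residuals, and with fry. Adjustment of list tests ran over 65 tests against baseline and 52 between successive time points.

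The lists were muscle-enriched, myeloid and lymphoid, the X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450, miR-17-92 and paralogous clusters, Dlk1-Dio3, let-7, miR-29, miR-30, fibroblast and smooth muscle, endothelial, erythroid, satellite cell and myoblast, epithelial, neuronal, and liver and endocrine miRNAs. The miRNAs named in the text followed a rule fixed before the data were examined. It took the 6 largest increases and the 6 largest decreases among passing miRNAs at each time point relative to U6, all measured members of the muscle-enriched, myeloid and lymphoid and X-linked lists, up to 4 members with the largest change of each other list, and the control RNAs. The rule gave 74 miRNAs, of which 54 are given with tested values. miR-203, miR-429, miR-680 and the members of imprinted loci outside Dlk1-Dio3 were named after their values were seen.

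The fit was tested on simulated data for day 1 against baseline over 217 assays in 20 runs. With U6 it recovered 20.2%, 76.8% and 99.2% of changes of log2 1, 2 and 4 and called 0.489% of unchanged miRNAs. With the median-miRNA scaling it recovered 77.5%, 94.3% and 99.0% and called 1.43%, against 6.71% with the median Ct, the alternative planned before. In these runs as many miRNAs were raised as lowered and U6 was left unchanged. A shift of U6 or of most miRNAs was therefore not covered. In further simulated data for day 1 against baseline, with a single list changed, the camera test called that list in 20 of 20 runs. It called other lists in 1 of 240 tests. Simulated values were drawn independently for each assay and well, so the test was not tried on list members that vary together.

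For the return to baseline, miRNAs shared by the comparisons were set against 100 simulated data sets with no change and against 6 splits of the 4 baseline values, each comparison then using its own 2. Alternatives covered the normalizer (each other control RNA, the median Ct, the median miRNA, quantile scaling and raw Ct), Ct limits of 32, 38 and none, undetermined wells set to 40, size thresholds of 1.5-fold and 4-fold, limma-trend, a plain t-test, only the 2 arms of a contrast in the fit, each value left out in turn, lists without second arms, and list medians against 10000 random lists of the same size from all tested miRNAs, not matched on expression. Raw Ct, the median miRNA and the estimated correlation were chosen after seeing the data. All assays were mouse assays, so an alternative restricted to them had nothing to change, and a mouse-number block was not run because the values carried no mouse numbers.

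Assay names were matched to gene symbols of the GRCm38.p6 annotation only to learn which miRNA genes neighbour each other: of the 217 assays, 173 matched 1 gene, 26 several and 18 none. No coordinates are given, since no build is named for the assays. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.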

Results

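The series followed the miRNAs of mouse tibialis anterior, a leg muscle, through injury and repair. Cardiotoxin, a snake venom peptide that lyses myofibres and leaves satellite cells able to rebuild them, was injected at 2.5 µM (100 µl) into C57BL/6J males aged 4 to 6 months. Muscles taken on days 1, 3, 4, 7 and 21 were each compared with uninjected baseline muscles, with 4 mice per time point per the labels. Muscles of days 2 and 5 were not analysed here. Levels were measured by TaqMan RT-PCR as threshold cycles (Ct), the PCR cycle at which a product becomes visible, so that a lower Ct means more RNA. Each arm held 4 Ct values for each of 217 miRNA assays and 5 control RNAs, and the same 4 baseline values served every time point. The files did not name the mouse behind a value, so the 4 values were taken as the 4 mice. If some were technical repeats, the p-values measure technical spread.

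Most assays gave a signal in every arm. With a limit of Ct 35 in at least 3 of 4 wells, 213 of the 217 miRNAs were detected at baseline, 214 at day 1, 216 at day 3, 217 at days 4 and 7, and 216 at day 21. Of the 888 wells per arm, 14 at baseline, 9 at day 1, 5 at day 3, 1 at day 4, 0 at day 7 and 6 at day 21 lay at or over that limit. A miRNA detected in only 1 of the arms compared is given as a bound, "at least N-fold".

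The control RNAs did not move together, which sets how every change below can be read. U6, a spliceosomal RNA marked in the files as the endogenous control, had a mean Ct of 14.8 ± 0.26 (SD, n = 4) at baseline and 12.5 ± 0.79 at day 1, then 13.0, 13.2, 13.6 and 14.6 at days 3, 4, 7 and 21. Over the same first interval Y1, a small cytoplasmic RNA, went from Ct 20.3 ± 0.58 to 22.7 ± 0.72, and the small nucleolar RNA snoRNA202 from 14.5 ± 0.34 to 14.3 ± 0.19. Relative to U6 the median miRNA therefore shifted by -1.95 on the log2 scale at day 1, -1.17 at day 3, -0.61 at day 4, -0.03 at day 7 and -0.12 at day 21. Changes are given relative to the median miRNA, with values relative to U6 for the main miRNAs. For every miRNA with a Ct in all wells the log2 change relative to U6 was lower than the printed value by the same amount, 1.91 at day 1, 1.12 at day 3, 0.67 at day 4, 0.09 at day 7 and 0.12 at day 21. A miRNA is said to have risen or fallen when it passed limma's test at an adjusted p under 0.05 under both scalings. The median of the residual SDs was 0.26 on the log2 scale relative to the median miRNA and 0.635 relative to U6.

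**Figure D1:**
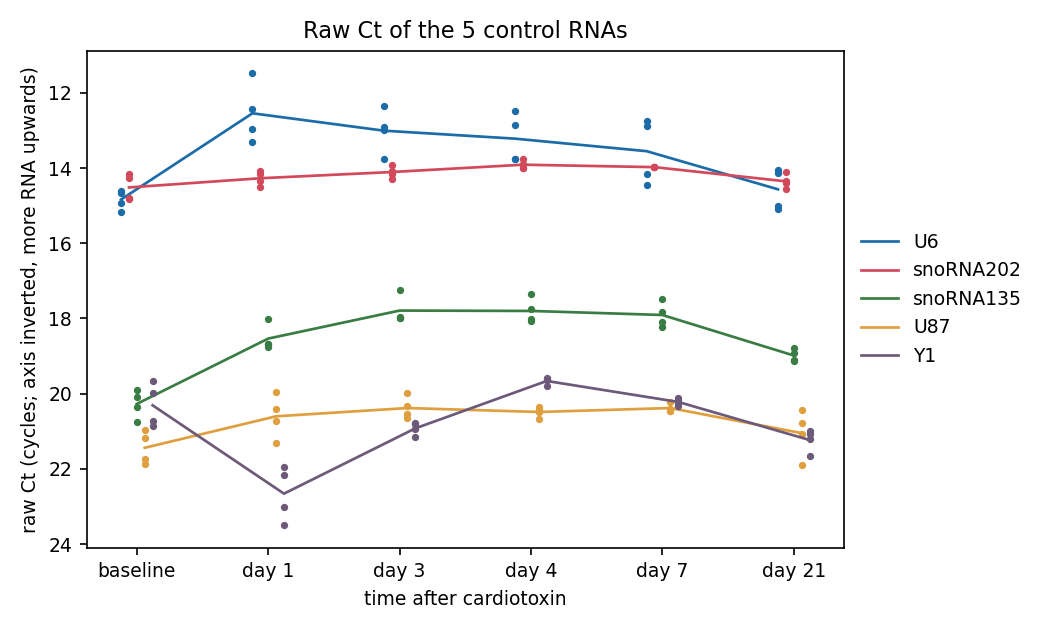
Raw Ct (cycles, axis inverted so that more RNA lies higher) of the 5 control RNAs at baseline and on days 1, 3, 4, 7 and 21, drawn at equal spacing, with a point for each of the 4 values per arm and lines through the means. U6 moved from a mean of 14.8 to 12.5 at day 1 while Y1 moved the other way, from 20.3 to 22.7.

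Day 1 asked what the muscle held in the days of fibre breakdown. The muscle-enriched miRNAs, which mark mature fibres, were already far down: miR-1 fell by 4.85 ± 0.47 on the log2 scale (SE, 4 values per arm), 28.8-fold lower than at baseline, and miR-133a fell by 3.06 ± 0.43. Some miRNAs of blood cells went the opposite way, although their list as a whole depended on the scaling. miR-223, abundant in neutrophils and other myeloid cells, rose 92.1-fold (log2 6.53 ± 0.12). miR-142-5p and miR-142-3p, made in haematopoietic cells, rose 34.7-fold and 31.1-fold. The epithelial miR-200 family also rose, with miR-200a 334-fold higher (8.38 ± 0.47), miR-141 42.3-fold, miR-200c 24.3-fold and miR-200b 12.3-fold. The mean baseline Ct of miR-200a was 34.52, close to the limit of 35, so its folds start near the limit of detection. Among miRNAs detected in both arms the largest rise was that of miR-685, at 499-fold (8.96 ± 0.77).

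Relative to U6 these day 1 changes were -6.75 for miR-1, -4.96 for miR-133a, 4.62 for miR-223, 3.21 for miR-142-5p, 6.47 for miR-200a and 7.05 for miR-685. miR-133b, miR-486 and miR-499, the last encoded within a slow myosin gene, fell by 2.92, 3.64 and 2.51 relative to the median miRNA. Among the other largest decreases, miR-107 fell by 3.48 and miR-365 by 3.47, and miR-489 and miR-29c fell by 1.46 ± 0.37 and 1.96 ± 0.43, while miR-34c rose by 3.17 ± 0.26 (1.26 relative to U6, a call lost in 2 of 8 runs that left out a value). miR-467c and miR-467d, from a large cluster inside the Sfmbt2 gene, rose 49.0-fold and 63.1-fold, and miR-18a, of the proliferation-associated miR-17-92 cluster, rose 15.0-fold. Bounds were at least 331-fold higher for miR-147, which macrophages make on toll-like receptor signalling, at least 149-fold higher for miR-429 and at least 674-fold higher for miR-680 (at least 88.2-fold, 39.7-fold and 179-fold relative to U6). In the other direction, miR-675-3p, processed from the imprinted H19 RNA, was at least 71.4-fold lower (268-fold relative to U6). At baseline 2 wells each of miR-147 and miR-680 and 1 of miR-429 still gave a Ct under the limit.

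As groups, all 5 measured muscle-enriched miRNAs fell at day 1, and 5 fell when adjusted over the list alone. Their camera test gave an adjusted p of 0.0462 relative to the median miRNA and 0.0225 relative to U6, against adjusted p = 0.435 and adjusted p = 0.834 with an estimated correlation. All 4 tested epithelial miRNAs rose (4 when adjusted over the list alone; camera adjusted p = 0.0351, and adjusted p = 0.403 with an estimated correlation). All 5 miR-30 miRNAs, a family abundant in differentiated tissue, fell, with miR-30c at -2.54 ± 0.17 and 5 calls when adjusted over the list alone (adjusted p = 0.0233, and adjusted p = 0.435 with an estimated correlation). Of the 29 tested miRNAs of the imprinted Dlk1-Dio3 cluster, 22 were lower and 1 higher relative to the median miRNA, with the same counts when adjusted over the list alone, and 28 were lower relative to U6. Its camera test gave adjusted p = 0.00106, and adjusted p = 0.403 with an estimated correlation. miR-370 of that cluster fell by 2.38 ± 0.68.

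Other lists depended on the scaling at day 1. Of 9 myeloid and lymphoid miRNAs, 7 were higher and 0 lower relative to the median miRNA (7 when adjusted over the list alone), but 3 higher and 2 lower relative to U6, and the camera test gave adjusted p = 0.0189, and adjusted p = 0.403 with an estimated correlation. All 11 miRNAs of the miR-17-92 and paralogous clusters were higher relative to the median miRNA (11 when adjusted over the list alone; camera adjusted p = 0.000904, and adjusted p = 0.403 with an estimated correlation), but 1 was higher and 1 lower relative to U6 (1 and 0 when adjusted over the list alone). For the let-7 family, which rises with differentiation, 5 of 9 were lower relative to the median miRNA (5 when adjusted over the list alone) and 9 of 9 relative to U6, with let-7f falling by 1.56 ± 0.12. The X-linked cluster of miR-322, miR-503 and miR-351 had 5 of 6 members higher relative to the median miRNA (5 when adjusted over the list alone) and 1 higher and 3 lower relative to U6 (1 and 2 when adjusted over the list alone), where miR-351 rose under both (3.97 ± 0.52).

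Over all 211 tested miRNAs, 87 were higher and 82 lower relative to the median miRNA, and 19 higher and 140 lower relative to U6, so that 51.5% and 11.9% of the calls were higher. With the other scalings that share ran from 23.0% (snoRNA135) to 98.9% (Y1), and 16 miRNAs were called lower relative to U6 but higher relative to the median miRNA. Relative to Y1 the medians of the Dlk1-Dio3, miR-30 and let-7 lists turned positive, at 1.69, 1.37 and 2.04, and miR-30c, miR-29c, miR-370, miR-489, miR-499 and let-7f lay above baseline.

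**Figure D2:**
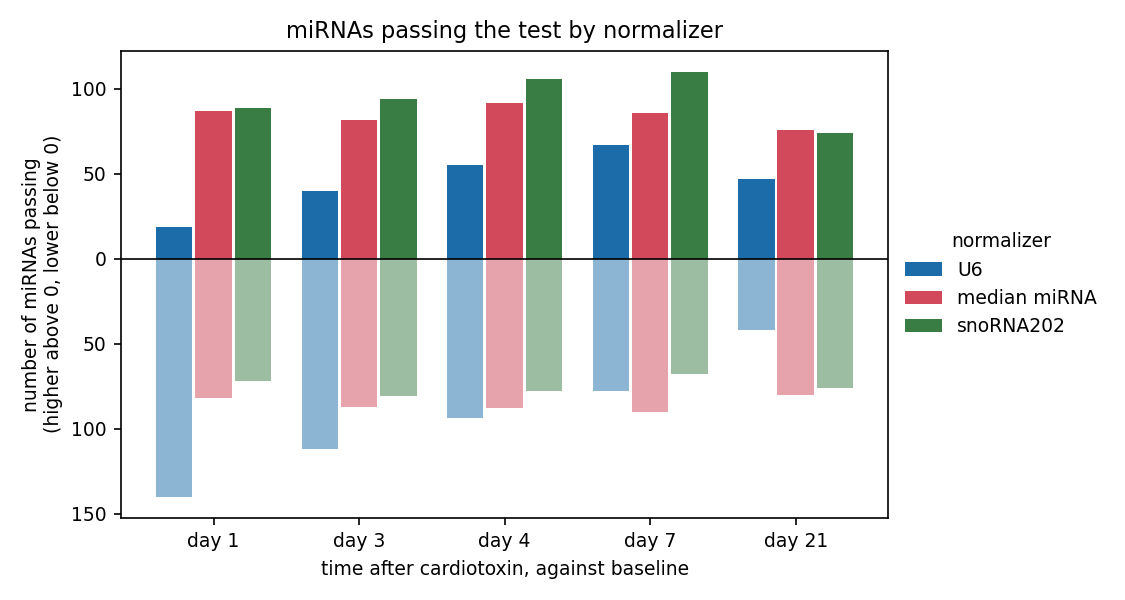
Number of miRNAs passing limma's test against baseline at each time point (higher above 0, lower below 0, 4 values per arm) with U6, the median miRNA or snoRNA202 as the normalizer. At day 1 the bars run from 19 higher and 140 lower with U6 to 87 higher and 82 lower with the median miRNA.

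Day 3 showed the deepest loss of fibre miRNAs. miR-1 fell by 6.20 ± 0.47, 73.4-fold under baseline, miR-133a fell by 5.87 ± 0.43, miR-486 fell by 6.08 ± 0.57 and miR-133b fell by 4.94 ± 0.29, and miR-499 was at least 305-fold lower (664-fold relative to U6). miR-489, known to keep satellite cells quiescent, fell by 5.42 ± 0.37, while miR-31, which holds back Myf5 translation in quiescent satellite cells, rose 74.8-fold (6.22 ± 0.24). miR-351 rose 160-fold (7.32 ± 0.52), and miR-34c, a p53 target, 36.0-fold (5.17 ± 0.26). The blood cell miRNAs miR-223 and miR-142-3p were still 13.4-fold and 16.4-fold over baseline.

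Relative to U6 these values were -7.32 for miR-1, -6.99 for miR-133a, -7.21 for miR-486, -6.54 for miR-489, 5.10 for miR-31, 6.20 for miR-351, 4.05 for miR-34c and 2.62 for miR-223. All 4 muscle-enriched miRNAs detected in both arms fell (4 when adjusted over the list alone; camera adjusted p = 0.0469, and adjusted p = 0.435 with an estimated correlation). All 5 miR-30 miRNAs fell (5 when adjusted over the list alone), with miR-30c 16.0-fold lower (adjusted p = 0.0117, and adjusted p = 0.403 with an estimated correlation). The epithelial list again had 4 of 4 up (4 when adjusted over the list alone), led by miR-200a at 7.65 ± 0.47 with miR-141 at 4.58, miR-200b at 3.29 and miR-200c at 2.58 (adjusted p = 0.0469, and adjusted p = 0.403 with an estimated correlation). miR-187 fell by 5.13 ± 0.74 and miR-193b by 4.29 ± 0.27.

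The Dlk1-Dio3 cluster was split at day 3, with 11 of 30 members higher and 6 lower relative to the median miRNA and 7 higher and 13 lower relative to U6, and the same counts when adjusted over the list alone. Its members miR-433, miR-665 and miR-370 rose by 4.95 ± 0.31, 3.81 ± 0.53 and 3.27 ± 0.68. Of 12 satellite cell and myoblast miRNAs, miR-31 was the only riser and 8 were lower relative to the median miRNA (11 relative to U6; the same counts when adjusted over the list alone), among them miR-26a, which acts on Ezh2 in myoblasts, at -2.78 ± 0.16. The smooth muscle miR-145 fell by 3.06 ± 0.16, the endothelial miR-126-3p by 2.05 ± 0.13 and miR-128a by 3.72 ± 0.17. In the X-linked cluster miR-503, which slows the myoblast cell cycle, rose by 2.13 ± 0.18 while its close neighbour miR-322 fell by 1.31 ± 0.18, although relative to Y1 it stood at 0.0075. miR-18a rose by 4.55 ± 0.15, and all 11 miRNAs of its list were higher relative to the median miRNA (11 when adjusted over the list alone; camera adjusted p = 0.00474, and adjusted p = 0.423 with an estimated correlation) but 1 relative to U6.

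Of 212 tested miRNAs, 82 were higher and 87 lower relative to the median miRNA at day 3 and 40 higher and 112 lower relative to U6, 48.5% and 26.3% of calls higher. The share ran from 18.5% (snoRNA135) to 76.7% (Y1) with other scalings, and the median of the Dlk1-Dio3 list was 0.18 relative to the median miRNA but -0.94 relative to U6, -1.59 relative to snoRNA135 and -0.56 after quantile scaling.

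By day 4 miR-351, of the X-linked cluster, and miR-433, of the imprinted Dlk1-Dio3 cluster, showed the largest increases among miRNAs detected in both arms. miR-351 stood 3341-fold over baseline (log2 11.71 ± 0.52), miR-433 425-fold (8.73 ± 0.31) and miR-431, also of the Dlk1-Dio3 cluster, 62.3-fold (5.96 ± 0.55). The folds of miR-351, here and at the other time points, start near the limit of detection at baseline, as do those of miR-433. miR-31 remained at 90.3-fold (6.50 ± 0.24), and miR-501-3p, encoded within the Clcn5 gene, rose 52.8-fold (5.72 ± 0.29). The fibre miRNAs were less far down, with miR-1 at -4.77 ± 0.47, miR-133a at -4.52 ± 0.43, miR-499 at -3.95 ± 0.47 and miR-486 at -2.56 ± 0.57. miR-30c had its lowest value relative to the median miRNA, -4.17 ± 0.17 (relative to U6 the lowest was at day 3), and miR-30e fell by 3.58 ± 0.18.

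Relative to U6 the day 4 changes were 11.03 for miR-351, 8.06 for miR-433, 5.29 for miR-431, 5.82 for miR-31, 5.05 for miR-501-3p, -5.44 for miR-1, -5.19 for miR-133a and -4.84 for miR-30c. In the Dlk1-Dio3 list 25 of 30 were higher and 2 lower relative to the median miRNA and 17 higher and 2 lower relative to U6, the same counts when adjusted over the list alone. Its camera test gave adjusted p = 0.000342, and adjusted p = 0.403 with an estimated correlation. miR-665 and miR-370 of this list rose by 5.24 ± 0.53 and 5.18 ± 0.68. miR-298, of the imprinted Gnas locus, was undetected in every baseline well and at least 3501-fold higher at day 4 (2195-fold relative to U6).

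In the X-linked list 4 of 6 were higher relative to the median miRNA (3 relative to U6; the same counts when adjusted over the list alone), with miR-503 at 3.68 ± 0.18 and miR-542-3p at 2.24 ± 0.22, although its camera test gave adjusted p = 0.143. All 5 muscle-enriched and all 5 miR-30 miRNAs fell (5 and 5 when adjusted over each list alone), with camera adjusted p = 0.104 and 0.00856, and adjusted p = 0.558 and adjusted p = 0.403 with an estimated correlation. The satellite cell list held 10 lower and 1 higher of 12 relative to the median miRNA (11 and 1 relative to U6; the same counts when adjusted over the list alone), including miR-489 at -3.12 ± 0.37 and miR-26a at -2.80 ± 0.16. miR-145 and miR-126-3p fell by 3.30 ± 0.16 and 2.65 ± 0.13, and miR-193b by 4.17 ± 0.27. miR-200a and miR-141 were still 78.9-fold and 10.2-fold over baseline, miR-223 4.43-fold, miR-18a 17.6-fold and miR-34c 34.3-fold.

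At day 4, 92 of 213 miRNAs were higher and 88 lower relative to the median miRNA, and 55 higher and 94 lower relative to U6, 51.1% and 36.9% of calls higher. Across the other scalings the share ran from 24.6% (snoRNA135) to 66.3% (raw Ct), and the X-linked median was 1.44 relative to the median miRNA but -0.09 relative to snoRNA135.

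Day 7 was marked by the imprinted Dlk1-Dio3 cluster, of which 30 of 30 tested miRNAs were higher than baseline relative to the median miRNA and 29 relative to U6 (30 and 29 when adjusted over the list alone). miR-433 rose 1017-fold (log2 9.99 ± 0.31), miR-431 254-fold (7.99 ± 0.55), miR-665 102-fold (6.67 ± 0.53) and miR-370 45.1-fold (5.50 ± 0.68). The mean baseline Ct of miR-665 was 34.25, so its folds, like those of miR-433, start near the limit of detection. The camera test of the list gave adjusted p = 2.65e-11 relative to the median miRNA, and adjusted p = 0.0291 with an estimated correlation. Relative to U6 these were 9.75e-14, and adjusted p = 0.469 with an estimated correlation. miR-351, miR-31, miR-501-3p and miR-34c remained high, at 405-fold, 78.8-fold, 50.0-fold and 35.5-fold over baseline, and miR-298 was at least 1599-fold higher (1499-fold relative to U6).

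The fibre miRNAs were recovering at day 7 but not back: miR-1 was at -3.29 ± 0.47, miR-133a at -3.11 ± 0.43 and miR-499 at -1.77 ± 0.47. miR-486 was at -1.20 ± 0.57, which passed relative to U6 (-1.29) but not relative to the median miRNA (adjusted p = 0.0552). The muscle-enriched list had 4 of 5 lower relative to the median miRNA and 5 of 5 relative to U6 (5 and 5 when adjusted over the list alone; camera adjusted p = 0.225). All 5 miR-30 miRNAs fell (5 when adjusted over the list alone), with miR-30c at -3.55 ± 0.17 and miR-30e at -3.24 ± 0.18 (camera adjusted p = 0.0104, and adjusted p = 0.403 with an estimated correlation). All 3 miR-29 miRNAs, which act on collagen and other matrix mRNAs, fell (3 when adjusted over the list alone; camera adjusted p = 0.21), with miR-29c at -3.72 ± 0.43 and miR-29a at -2.16 ± 0.19. miR-135a fell by 3.91 ± 0.21 and miR-101a by 3.29 ± 0.16.

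Vessel and stromal miRNAs divided at day 7. miR-126-3p and miR-126-5p, of endothelium, fell by 2.24 ± 0.13 and 2.44 ± 0.20, and miR-143 and miR-145, of smooth muscle, by 2.39 ± 0.17 and 3.19 ± 0.16, whereas miR-199a-5p, of fibroblasts, rose by 2.24 ± 0.84. The fibroblast and smooth muscle list had 4 of 6 higher and 2 lower (3 and 2 relative to U6; the same counts when adjusted over the list alone), and the endothelial list 1 of 4 higher and 3 lower (0 and 2 relative to U6; the same counts when adjusted over the list alone). Blood cell miRNAs were mixed: miR-142-3p, miR-142-5p and miR-342-5p rose by 2.19 ± 0.23, 2.11 ± 0.15 and 3.02 ± 0.39, but the lymphocyte miR-150 fell by 2.10 ± 0.21 and the red cell miR-451 by 2.09 ± 0.36. In the X-linked list 5 of 6 were higher and 1 lower (4 and 1 relative to U6; the same counts when adjusted over the list alone), with miR-503, miR-542-3p and miR-542-5p up by 2.36, 2.54 and 1.62 and miR-322 down at -1.25 ± 0.18. miR-200a and miR-141 were 42.3-fold and 5.59-fold over baseline.

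Relative to U6 the day 7 values were 9.90 for miR-433, 7.90 for miR-431, 8.57 for miR-351, 6.21 for miR-31, -3.38 for miR-1, -3.20 for miR-133a, -3.64 for miR-30c and -3.81 for miR-29c. Over 213 miRNAs, 86 were higher and 90 lower relative to the median miRNA and 67 higher and 78 lower relative to U6, 48.9% and 46.2% of calls higher, with 28.3% (snoRNA135) to 75.5% (Y1) under the other scalings. After quantile scaling miR-141 turned to -0.78, and leaving out single values ended the calls relative to U6 of miR-322 (4 of 8 runs), miR-199a-5p (3), miR-486 (1) and miR-499 (1).

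**Figure D3:**
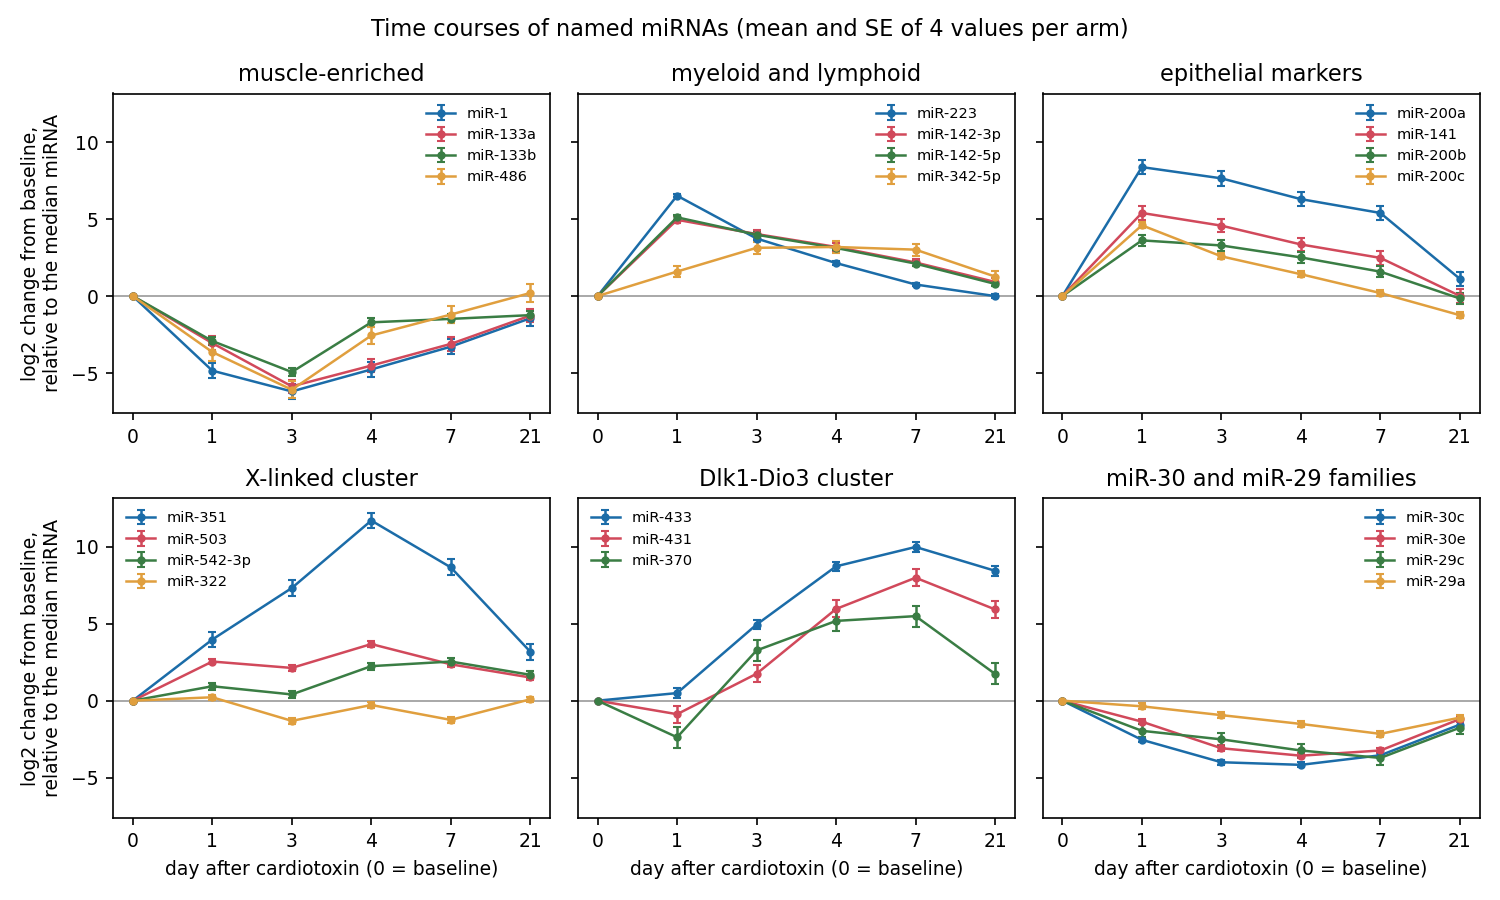
Log2 change from baseline relative to the median miRNA (points, with limma's SE, 4 values per arm) for named miRNAs of 6 groups, with days 1, 3, 4, 7 and 21 at equal spacing. miR-1 reaches its lowest point at day 3 (-6.20), miR-351 peaks at day 4 (11.71) and miR-433 at day 7 (9.99). Relative to U6 the day 1 points lie lower by about the day's median shift of 1.95, and relative to Y1 miR-30c, miR-29c and miR-370 lie above baseline at day 1.

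At day 21 the muscle was compared with baseline for what had not returned. The imprinted cluster had not: 28 of 30 Dlk1-Dio3 miRNAs were still higher relative to the median miRNA and 27 relative to U6 (28 and 27 when adjusted over the list alone), with miR-433 at 348-fold (8.44 ± 0.31), miR-431 at 61.0-fold (5.93 ± 0.55) and miR-665 at 27.3-fold. The satellite cell miRNA miR-31 stayed 90.6-fold over baseline (6.50 ± 0.24), miR-501-3p 39.9-fold, miR-34c 23.8-fold and miR-351 9.09-fold. Some fibre miRNAs remained low, with miR-133a at -1.27 ± 0.43, miR-133b at -1.24 ± 0.29 and miR-499 at -2.07 ± 0.47. miR-486 was at 0.20 ± 0.57 and miR-223 at 0.00 ± 0.12, neither of which passed, although miR-223 passed relative to Y1 (1.07).

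miR-1 was at -1.44 ± 0.47 at day 21, which passed relative to the median miRNA (adjusted p = 0.00979) but not relative to U6 (-1.56, adjusted p = 0.0513). In the muscle-enriched list 4 of 5 were lower relative to the median miRNA (4 when adjusted over the list alone) and 3 relative to U6 (4 when adjusted over the list alone; camera adjusted p = 0.262 and 0.141). The Dlk1-Dio3 camera test gave adjusted p = 1.03e-12, and adjusted p = 0.0279 with an estimated correlation. Relative to U6 it gave 1.86e-16, and adjusted p = 0.469 with an estimated correlation. All 5 miR-30 miRNAs were lower relative to the median miRNA (5 when adjusted over the list alone) and 3 relative to U6 (5 when adjusted over the list alone), with miR-30c at -1.56 ± 0.17 (camera adjusted p = 0.0353, and adjusted p = 0.435 with an estimated correlation). All 3 miR-29 miRNAs fell (3 when adjusted over the list alone; camera adjusted p = 0.14), miR-29c by 1.76 ± 0.43, miR-29b by 1.41 ± 0.19 and miR-29a by 1.10 ± 0.19.

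The largest decreases at day 21 were those of miR-187 (-3.42 ± 0.74), miR-129-3p (-2.90 ± 0.69), miR-135a (-2.59 ± 0.21), miR-125b-3p (-2.36 ± 0.38), miR-499 and miR-345-3p (-2.05 ± 0.38). miR-101a fell by 1.67 ± 0.16, miR-145 by 1.41 ± 0.16, miR-365 by 1.52 ± 0.29 and miR-685 by 1.74 ± 0.77. Of the miR-200 family, miR-200c had gone from its early rise to 1.24 ± 0.19 under baseline. In the X-linked list 5 of 6 were higher relative to the median miRNA and 4 relative to U6 (5 and 4 when adjusted over the list alone; camera adjusted p = 0.0593), with miR-503 at 1.51 ± 0.18. miR-370 was at 1.74 ± 0.68, and miR-298 at least 17.1-fold higher (15.7-fold relative to U6).

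Relative to U6 the day 21 values were 8.32 for miR-433, 6.38 for miR-31, 5.81 for miR-431, -1.39 for miR-133a, -2.19 for miR-499 and -1.68 for miR-30c. Over 213 miRNAs, 76 were higher and 80 lower relative to the median miRNA and 47 higher and 42 lower relative to U6, 48.7% and 52.8% of calls higher, with 20.2% (snoRNA135) to 94.7% (Y1) under the other scalings. Leaving out single values ended the calls relative to U6 of miR-133a (4 of 8 runs), miR-365 (5), miR-370 (6) and miR-685 (4).

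**Figure D4:**
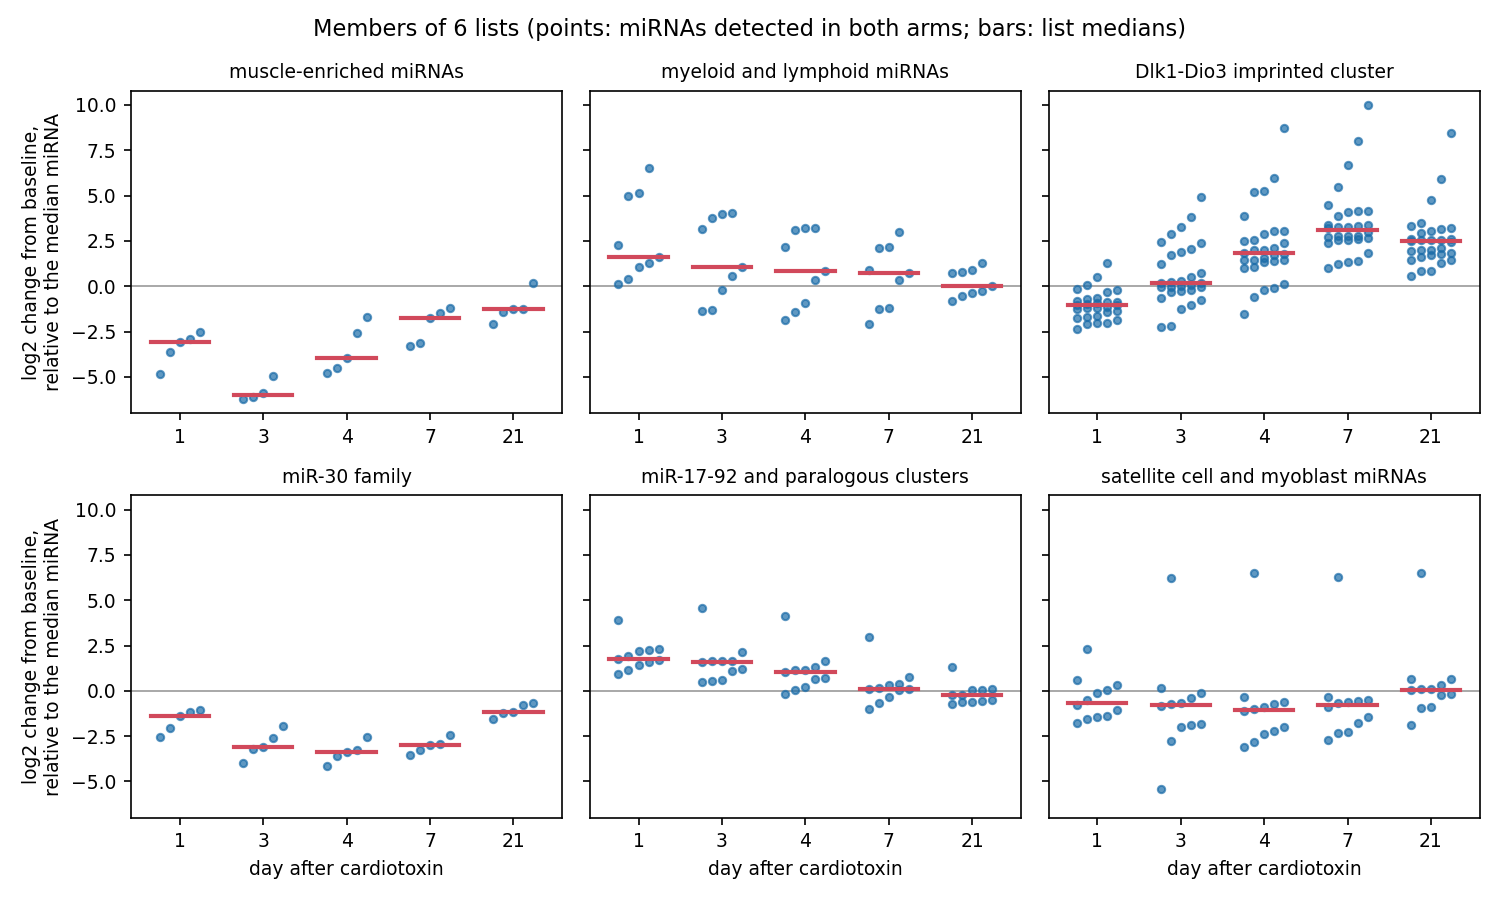
Log2 change from baseline relative to the median miRNA (points, miRNAs detected in both arms; bars, list medians; 4 values per arm) for the members of 6 lists on days 1, 3, 4, 7 and 21. The muscle-enriched median lies at -5.98 on day 3 and the Dlk1-Dio3 median at 3.12 on day 7. The day 3 median of the Dlk1-Dio3 list and the early medians of the miR-17-92 list differ in sign between scalings.

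Remaining lists were weaker. The neuronal miRNAs had 1 of 3 lower at day 1, 2 at day 3, 3 at day 4, 1 at day 7 and 1 at day 21 relative to the median miRNA, the same counts when adjusted over the list alone, and 3, 3, 3, 0 and 0 relative to U6. The let-7 list had 3 higher and 2 lower of 9 at day 21 (the same when adjusted over the list alone), and the myeloid and lymphoid list 4 higher and 3 lower of 9, with camera adjusted p = 0.888 and 0.939. Of the erythroid list only miR-451 was measured, and no member of the liver and endocrine list was measured here. Of the 65 list tests against baseline, 15 passed relative to U6 with the preset correlation, 9 against random lists of the same size and 0 with an estimated correlation. Relative to the median miRNA, 2 held with an estimated correlation, those of the Dlk1-Dio3 cluster at days 7 and 21.

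Successive time points showed when groups moved. Between days 1 and 3 the Dlk1-Dio3 cluster climbed, with 25 of 29 members higher and 2 lower relative to the median miRNA and 26 higher relative to U6 (the same counts when adjusted over the list alone), while all 4 muscle-enriched miRNAs tested were lower (3 relative to U6). Between days 3 and 4 all 4 muscle-enriched miRNAs and all 6 X-linked miRNAs rose, under both scalings and when adjusted over each list alone, and 28 of 30 Dlk1-Dio3 miRNAs were higher (26 relative to U6; 28 and 29 when adjusted over the list alone). Between days 4 and 7, 24 of 30 Dlk1-Dio3 miRNAs were higher under both scalings (24 relative to the median miRNA and 27 relative to U6 when adjusted over the list alone), whereas 11 of 11 miR-17-92 miRNAs were lower relative to the median miRNA and 0 relative to U6. Between days 7 and 21 all 5 miR-30 miRNAs rose and all 4 tested epithelial miRNAs fell under both scalings, and 10 of 12 satellite cell and myoblast miRNAs were higher relative to the median miRNA and 5 relative to U6 (10 and 6 when adjusted over the list alone).

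With an estimated correlation the Dlk1-Dio3 tests relative to the median miRNA gave adjusted p = 0.0261 for day 3 against day 1, adjusted p = 0.00883 for day 4 against day 3 and adjusted p = 0.00883 for day 7 against day 4, and the X-linked test adjusted p = 0.00883 for day 4 against day 3. In the same order of intervals, with day 21 against day 7 last, 97, 52, 45 and 75 miRNAs passed relative to U6 and 170, 117, 108 and 153 relative to the median miRNA. The share of calls that were higher was 72.2%, 92.3%, 95.6% and 53.3% relative to U6 and 39.4%, 47.9%, 48.1% and 54.2% relative to the median miRNA. With the other scalings it ran from 7.30% (Y1) to 51.0% (quantile), from 12.3% (Y1) to 87.9% (U87), from 44.4% (quantile) to 96.4% (Y1) and from 9.49% (raw Ct) to 56.0% (snoRNA135), and snoRNA202 gave 43.4%, 53.6%, 72.4% and 25.0%.

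The extent of return was counted from the miRNAs that changed at least 2-fold and passed at any of days 1 to 7. Of 192 such miRNAs relative to the median miRNA, 102 lay within 2-fold of baseline at day 21, 65 of them with a 95% interval inside 2-fold, and 90 still passed at 2-fold or more. Relative to U6, 97 of 190 lay within 2-fold, 12 with the interval inside, and 81 still passed. With snoRNA135 as the normalizer the number within 2-fold was lower, at 59. Among those within 2-fold relative to the median miRNA were miR-223 and miR-486, the latter with an interval reaching past 2-fold, and among those still apart miR-433, miR-31 and miR-431. Up both by day 7 and at day 21 were 53 miRNAs relative to the median miRNA, where independent lists would share 30.5, simulated unchanged groups shared 0 and splitting the baseline values between the comparisons gave 50.7, with 28.3 for independent lists of the split sizes. Down in both were 31, against 18.6, 0 and 29.7, the last with 18.1 for independent lists. Relative to U6 the numbers were 43 up (16.1, 0 and 37.3 with 13.2) and 34 down (26.8, 0.04 and 17.7 with 15.0), so that the downward overlap was little above independence once the baseline was split. The simulated groups say little about the shared baseline, since they held too few calls to overlap. Relative to the median miRNA they held on average 0.08 miRNAs up by day 7 and 0.01 at day 21 (5.49 and 1.66 relative to U6).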

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

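The tests of the 3 weighed patterns, the splits of values relative to U6 and the median-miRNA scaling itself were chosen after the results had been seen, and only the reading of the splits under that scaling was written before those splits were run. Each pattern below was set against the technical and biological readings that could be tested with these values.

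At day 1 most miRNAs were lower relative to U6, and 3 readings were tested. Less RNA or poorer cDNA in the day 1 wells would move every control alike, but the changes in mean raw Ct of the 5 control RNAs ranged over 4.64 cycles. Such a loss was therefore not the only change. An equal loss on top of other changes would leave that range as it is, so it is not excluded. A rise of U6 itself could explain the pattern, since U6 was 1.91 ± 0.39 higher relative to the median miRNA, 2.05 ± 0.44 relative to snoRNA202, 1.46 ± 0.42 relative to U87 and 4.64 ± 0.42 relative to Y1, but 0.555 ± 0.335 relative to snoRNA135, which itself rose by 1.35 ± 0.15 relative to the median miRNA, so the tests cannot tell. A fall of the whole miRNA class would need raw Ct to rise, and the median raw Ct changed by -0.384 ± 0.147 cycles, but the RNA input is not stated, so this also stays open. That injury itself moved U6 or the class remains possible and was not tested.

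The rise of miR-200a, miR-200b, miR-200c, miR-141 and miR-429 at day 1 was unexpected in muscle. A single epithelial source of fixed composition was tested at day 7, when miR-200a kept 12.9% of its gain. With its baseline part taken as unchanged, miR-200c would then stand at 1.95, but it stood at 0.20 ± 0.19. That part may itself have fallen, since miR-200c lay under baseline at day 21, so such a source is not excluded for miR-200c. miR-200b and miR-141 lay within 2 SE of their expected values (larger difference 0.40), so for these such a source also stays open. Skin cannot be told apart by its marker miR-203, which changed by -0.50 ± 0.18 but was abundant at baseline (mean Ct 21.9), where a small share would be hidden. The day 1 and baseline wells of the 5 miRNAs did not overlap, with a smallest gap of 2.69 cycles. Since these miRNAs were picked for their rise, the gap is no separate test of noise in single wells. Expression within cells of the injured muscle may also explain the pattern and was not tested.

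miR-351 rose more than its neighbours in the X-linked cluster at day 4. An equal gain of molecules at day 4, hidden by higher baselines, cannot be told apart: the median shortfall over 5 neighbours was 3.96, but this compares levels between assays whose efficiencies were not measured, and miR-503 came close (expected 3.75, observed 3.68). An equal gain on both days 4 and 7 was followed within each assay, with baseline levels taken as unchanged. miR-351 kept 12.1% of its gain at day 7. Against the change expected from that share, 4 neighbours lay above. miR-322, which had no gain at day 4, lay 1.22 below that change. The median was 1.08, and 0.74 at the share plus 2 SE. At that upper share miR-542-3p, miR-542-5p and miR-450a-5p lay 1.60, 1.43 and 0.74 above, which argues against an equal gain for them. miR-503 lay 0.39 above, within 2 of the largest SE (0.219), so for it an equal gain stays open. The lowest baseline Ct of miR-351 and its highest day 4 Ct lay 10.97 cycles apart. Since miR-351 was picked for its large rise, this gap is no separate test of noise. Noise near the detection limit at baseline may still affect the size of its fold. Separate processing or stability of miR-351 might explain the difference and was not tested.

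Among 197 groups of 4 values of the named miRNAs, Dixon's test at a rate of about 1 in 20 picked 8 values, where 9.85 were expected by chance. As delta Ct relative to U6, with the nearest other value, they were miR-499 on day 21 (13.2, nearest 15.18), miR-142-5p on day 3 (8.97, nearest 10.02), miR-200c at baseline (11.12, nearest 12.26), miR-200b at baseline (15.96, nearest 14.45), miR-351 on day 1 (15.56, nearest 17.42), miR-370 on day 3 (12.25, nearest 13.28), miR-322 on day 3 (7.18, nearest 8.23) and miR-451 on day 7 (6.40, nearest 7.96). In addition 1 of the 4 day 4 wells of miR-99b, a miRNA otherwise well detected, stood at the last cycle, Ct 40, with the next highest at 21.38.

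Changes from baseline differed between successive time points for 97 miRNAs (day 3 against day 1), 52 (day 4 against day 3), 45 (day 7 against day 4) and 75 (day 21 against day 7) relative to U6. Regrouping the 8 values of a comparison in all 35 ways asked whether chance alone gives as many. For day 3 against day 1 only the true grouping gave as many (1 of 35 splits, with at most 2 in any other). Other splits also did so for day 4 against day 3 (2 of 35, up to 64), day 7 against day 4 (3 of 35, up to 150) and day 21 against day 7 (2 of 35, up to 151). In these chance was not excluded. In those 3 comparisons the highest other splits differed in mean U6 Ct by 0.848, 1.29 and -1.22 cycles. For day 3 against day 1 the highest other split differed by 0.9325 cycles and gave 2 calls. Whether the spread of U6 between wells gave the high counts was not tested.

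Against baseline, only the true grouping reached the true counts relative to U6 at each time point (1 of 35 splits). These counts were 159, 152, 149, 145 and 89 miRNAs on days 1, 3, 4, 7 and 21. The highest other splits gave 129, 113, 68, 77 and 2. Relative to the median miRNA only the true grouping did so in all 9 comparisons (1 of 35 each). The true counts there were 169, 169, 180, 176 and 156 against baseline with at most 44, 76, 53, 4 and 2 otherwise. Between successive time points they were 170, 117, 108 and 153 with at most 54, 17, 37 and 2. With 35 splits, 1 of 35 is the smallest share possible, and it was not adjusted over the comparisons. Mixed splits also carry the difference between arms as spread within their groups. These counts therefore do not by themselves exclude chance.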

How the results depend on the processing

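Of 143 printed miRNA changes relative to U6, 141 kept their call and direction relative to the median miRNA, 140 with snoRNA202, 140 with the median Ct, 142 with U87, 138 on raw Ct, 135 with snoRNA135, 128 after quantile scaling and 114 with Y1. Ct limits of 38 or none and undetermined wells set to 40 changed 0 of the 143, a limit of 32 changed 0 of the 116 it left, limma-trend kept 142, a plain t-test 138 and a fit of 2 arms 140. A rise or fall was printed as such only where it passed under both U6 and the median miRNA, so the 141 is largely set by that rule. The printed values also favour large changes. Of all 363 values of the 74 named miRNAs over the 5 days, 268 kept call and direction relative to the median miRNA, with 24 turning direction. The number was 284 with snoRNA135 (10 turning), 257 with snoRNA202 (36 turning), 232 on raw Ct (58 turning) and 194 with Y1 (86 turning). Raw Ct, the median miRNA and the estimated correlation were chosen after seeing the data.

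With Y1 as the normalizer 8 printed changes turned positive: let-7f (1.17), miR-29c (0.775), miR-30c (0.19), miR-370 (0.355), miR-489 (1.27) and miR-499 (0.22) on day 1, miR-322 on day 3 (0.0075) and miR-223 on day 21 (1.07). After quantile scaling miR-141 on day 7 turned to -0.78. With single values left out, 1112 of 1144 refits kept the call, 30 lost it and 2 gained it. The losses, of 8 runs each, fell on miR-370 (6), miR-365 (5), miR-133a (4) and miR-685 (4) on day 21, miR-322 (4), miR-199a-5p (3), miR-486 (1) and miR-499 (1) on day 7, and miR-34c (2) on day 1.

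The number of miRNAs passing between days 7 and 21 was 75 with U6, 158 on raw Ct, 150 with the median Ct, 153 with the median miRNA, 142 after quantile scaling, 141 with snoRNA135, 152 with snoRNA202, 115 with U87, 122 with Y1, 40 with 2 arms in the fit and 10 with a plain t-test. Between days 1 and 3, 97 became 153 on raw Ct, 169 with the median Ct, 170 with the median miRNA, 153 after quantile scaling, 159 with snoRNA135, 166 with snoRNA202 and 178 with Y1. Between days 3 and 4, 52 became 84, 154, 117, 129, 82, 110 and 163 in that order of settings. Between days 4 and 7, 45 became 99, 104, 108, 108, 101, 116 and 110, and 4 with a plain t-test. At day 21 against baseline, 89 became 138 on raw Ct, 154 with the median Ct, 156 with the median miRNA, 135 after quantile scaling, 173 with snoRNA135 and 150 with snoRNA202. The 97 miRNAs back within 2-fold became 59 with snoRNA135 and 53 at 1.5-fold. The 15 list shifts became 0 with an estimated correlation, and 2 with it relative to the median miRNA, and 9 (all among the 15) when list medians were set against 10000 random lists from all assays. For these counts the cause was not tested.

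Leaving out single values, counts against baseline ranged over 148 to 159 (day 1), 135 to 155 (day 3), 138 to 143 (day 4), 127 to 145 (day 7) and 76 to 90 (day 21). Successive counts ranged over 87 to 97 (day 3 against day 1), 37 to 55 (day 4 against day 3), 33 to 69 (day 7 against day 4, highest without value 4 of day 7) and 50 to 83 (day 21 against day 7, lowest without value 4 of day 7). The list shifts ranged over 14 to 15 and the return count over 92 to 98. Of the 65 list shifts against baseline, each the list median minus the median of the other miRNAs, 60 kept call and direction relative to the median miRNA. None that passed turned direction under another normalizer, although list medians themselves did. Every normalizer but quantile scaling moves all miRNAs of a well alike, which cancels in this difference. A direction could therefore hardly turn, and that none did says little about the normalizer.

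No paired analysis was possible because the files number no mice and different mice were taken at each time point. A restriction to mouse assays and a mouse-number block were not run, since all assays were mouse assays and no mice were numbered. With a Ct limit of 32 the detected miRNAs were 206 at baseline and 210, 214, 217, 217 and 211 on days 1, 3, 4, 7 and 21.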

Other observations

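The tests in this part were chosen after the values had been seen. miRNAs of imprinted loci other than Dlk1-Dio3 also stood high on day 7. miR-675-3p, processed from H19, was at 4.47 relative to the median miRNA, miR-296-5p of the Gnas locus at 3.32, miR-335-3p and miR-335-5p of the Mest locus at 3.65 and 3.23, and miR-298 was at least 1599-fold higher. From the Sfmbt2 locus miR-467d was at 3.14, miR-467c at 2.75, miR-467a at 1.77 and miR-669a at 0.89, while miR-467b (0.19) and miR-467e (0.82) did not pass. The highest value came on day 4 or later for 5 of these 11 miRNAs, all 5 of the H19, Gnas and Mest loci and 0 of the 6 of Sfmbt2, so a late rise was not seen at all of these loci. Relative to U6, miR-467e and miR-669a of Sfmbt2 were also highest on days 4 and 7 (0.99 and 0.80), where neither passed. At day 1, 5 of 6 Sfmbt2 miRNAs were higher relative to the median miRNA (3 higher and 1 lower relative to U6), and of 3 tested H19, Gnas and Mest miRNAs 1 was higher and 2 lower (0 and 2 relative to U6). The members were partly chosen with their values in view, and miR-669a did not pass at day 7 relative to U6.

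miRNA genes that lie near each other tended to move together, with exceptions. Over 42 pairs within 10 kb outside the Dlk1-Dio3 cluster the median Pearson r of the 5 changes was 0.796, where shuffled pairs gave 0.324 at their 95th percentile and 0 of 1000 shuffles reached the real value. Of the 42 pairs 8 had a negative r, among them let-7e with miR-99b (-0.490), miR-322 with miR-351 (-0.481) and miR-351 with miR-542-5p (-0.394). With the Dlk1-Dio3 pairs included the median was 0.888 over 150 pairs. Shared transcription of neighbours might give such values, and this was not tested.

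On day 7 the 4 Ct values of snoRNA202 had an SD of 0.00577 cycles, while those of U6 in the same arm had an SD of 0.87.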
